A study of Parabronema skrjabini with 4 samples.

How the data were processed

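Polyadenylated RNA of the parasitic nematode Parabronema skrjabini was sequenced at 4 developmental stages, namely egg, infective larva (L3), adult female and adult male, with 1 library per stage. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, selected on oligo(dT) beads and fragmented. A 5' adaptor was ligated to the RNA fragments before random-primed reverse transcription, and the libraries were read as paired ends on an Illumina NextSeq and an Illumina HiSeq system. Which library was read on which instrument, and at which read length, is not given in the sources used here, so instrument and stage could not be separated. The labels give each sample's stage. The title of the L3 sample also contains the word egg, and its stage was taken from the source and stage labels, both of which give L3 larvae.

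The authors deposited 1 table of RPKM values (reads relative to transcript length and to the library's total) with 54102 assembled transcripts, 4 library columns and the length of each transcript. Bowtie and edgeR are named, with no role, version or setting, per the submitters' processing notes. The assembler, the counting rule, the treatment of reads with several matches and any filter are not given in the sources used here. No genome was used here, so no transcript is given a genomic position. The deposited table pairs none of the 54102 transcripts with a gene name (0 names), and the transcripts can be reported only by identifier. For that reason the 25 gene lists written before the data were examined (major sperm proteins, vitellogenins, cuticle collagens, cell cycle, proteases, antioxidants, energy metabolism, host, fly vector and microbial transcripts, among others) could be applied to no transcript, and 0 list results are given. The identifiers carry a component, a gene and an isoform field and 1 of 2 endings. 15563 of them end in L3s (28.8%, here L3-ending) and 38539 end in other (71.2%, here other-ending). The endings are read here as a name only, since no source used here defines them.

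The shares of reads computed from RPKM and transcript length summed to 1 in each column, so the deposited RPKM values are relative to the reads on the listed transcripts alone. These shares are whole multiples of 1 step per library, which gives the number of counted reads (or read pairs, if pairs were counted as 1). The step was fitted on short transcripts with few reads. With it, 99.99% of the non-zero egg values, 95.9% of the L3 values, 98.6% of the female values and 98.4% of the male values came within 0.1 of a whole read, and at least 99.9% in each library were whole within the rounding of the table to 2 decimals. The recovered totals were 3033150 reads for egg, 13124605 for L3, 9104030 for adult female and 9601660 for adult male. At the median transcript length of 522 nt, 1 read was worth 0.632 RPKM in egg, 0.146 in L3, 0.210 in the female and 0.200 in the male library. A count of 0 reads allows up to 3 reads, or 1.89, 0.438, 0.631 and 0.599 RPKM at that length in the same order.

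With 1 library per stage there is no replicate error, no test was made and no p-value is given. Every comparison describes 2 libraries. A transcript was called higher in 1 library when its log2(RPKM + 1) exceeded that of the other by at least 2, which is 4-fold, with RPKM of at least 1 in the higher library. The pseudocount of 1 RPKM understates the change of low transcripts. All 6 pairs of stages were compared. Intervals on a ratio of reads are exact (Clopper-Pearson) 95% intervals. They cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. A ratio against 0 reads is given as a lower bound computed against 3 reads in that library. The transcripts named are, per comparison and direction, the 2 with the largest log2 difference among those with RPKM of at least 10 in the higher library, plus the 2 highest per stage. This rule, the thresholds and the first set of alternatives were fixed before the data were examined. The same reads gave the choice and the folds, so the choice favours low counts in the lower library. The 95% level and the lower bounds may not hold for transcripts so chosen. Transcripts with the same component number can share reads. By component, gene field and ending, leaving out the isoform field, the 54102 transcripts fall into 46998 units, of which 41759 hold 1 transcript, and sums over isoforms were taken over these units.

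The procedure was tested on simulated data with Poisson reads for all 54102 transcripts, of which 200 were changed 8-fold. Apart from these, both libraries of a pair were drawn from the same mean levels, with counting error only. Calls on unchanged transcripts therefore do not give the rate of false calls between real libraries. In the simulated male against female comparison 152 of the 200 were called (76.0%), with 1 unchanged transcript called higher in male and 2 in female. In the simulated female against egg comparison 161 were called (80.5%), with 81 unchanged transcripts called higher in female and 14 in egg. In the other 4 comparisons between 149 and 166 of the 200 were called. Calls on unchanged transcripts numbered 69 and 6 for L3 against egg (higher in L3 and in egg) and 76 and 23 for male against egg, but at most 2 per direction for either adult against L3. Alternatives were other pseudocounts, filters, fold thresholds and scalings, and, added after the data were seen, a minimum of 10 reads, thinning of all libraries to the egg depth, summing over isoforms, pairwise scaling, use of the other-ending transcripts alone and omission of the L3 library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.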

Results

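The series measured gene expression in Parabronema skrjabini, a nematode parasite of camels, at 4 points of its life: egg, infective L3, adult female and adult male. Each stage was represented by 1 library, with 3033150 reads for egg, 13124605 for L3, 9104030 for adult female and 9601660 for adult male on 54102 assembled transcripts of up to 12805 nt. There are no replicates, so differences are between libraries and have no replicate check. At RPKM of at least 1, 24070 transcripts were detected in egg, 20123 in L3, 29882 in the female and 29574 in the male library. Of the transcripts detected, 8229 in egg, 1201 in L3, 6670 in the female and 6209 in the male library rested on fewer than 10 reads. No read was counted for 25247 transcripts in egg (46.7%), 15652 in L3 (28.9%), 12784 in the female (23.6%) and 12047 in the male (22.3%).

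The L3 library stood apart from the other 3 in which transcripts its reads fell on. L3-ending transcripts took 91.0% of the L3 reads (exact 95% interval 90.98 to 91.01), but 7.22% of the egg reads (7.19 to 7.25), 3.32% of the female reads (3.31 to 3.33) and 2.20% of the male reads (2.19 to 2.21). Of the 15563 L3-ending transcripts, 1 had no read in L3, whereas 11162 had none in egg (71.7%), 8690 none in the female (55.8%) and 8968 none in the male library (57.6%). Of the 38539 other-ending transcripts, 15651 had no read in L3 (40.6%) and 14085 none in egg (36.5%), against 4094 in the female (10.6%) and 3079 in the male (7.99%). Only 4940 transcripts reached RPKM of at least 1 in all 4 libraries, and 909 of these lay within 4-fold in all 4. Among egg, female and male alone, 10347 transcripts reached RPKM of at least 1 in each and lay within 4-fold.

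**Figure D1:**
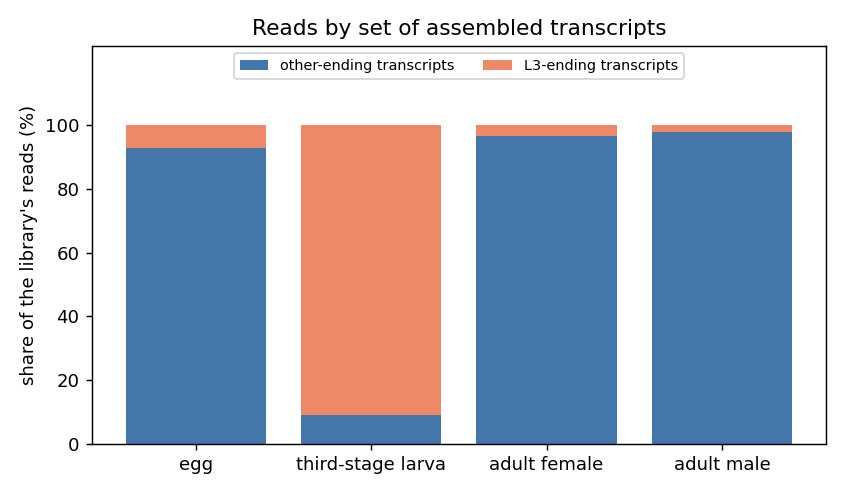
Share of each library's reads (y axis, %) on other-ending transcripts (blue) and L3-ending transcripts (orange), for the 4 libraries on the x axis. The L3 bar is 91.0% orange, while the orange part of the egg, female and male bars is 7.22%, 3.32% and 2.20%.

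The 10 transcripts with most reads held 17.4% of the egg reads, against 9.10% in L3, 5.81% in the female and 4.23% in the male library. The 100 with most reads held 34.9% in egg and 31.9% in L3, against 17.4% in the female and 15.9% in the male. The transcripts named next rank highest by RPKM, which is relative to length, so those with most reads can differ. In egg the highest, c40802_g1_i1_other (388 nt), reached 99436 RPKM, or 3.86% of the egg reads. It had 1321 RPKM in L3, 1213 in the female and 745 in the male. The next, c64680_g1_i6_other (767 nt), had 47134 RPKM in egg, 476 in L3, 19.1 in the female and 3.12 in the male. In L3 the highest transcripts were c28583_g1_i1_L3s (492 nt), with 10573 RPKM, and c7041_g1_i1_L3s (688 nt), with 9086 RPKM. In the female they were c64913_g1_i3_other (2275 nt), with 6860 RPKM, and c56208_g1_i1_other (308 nt), with 5917 RPKM. Both were also abundant in the male, at 3157 and 1631 RPKM, and the former had 12068 RPKM in egg. In the male they were c55289_g2_i1_other (324 nt), with 15990 RPKM, and c60056_g2_i1_other (435 nt), with 13374 RPKM. These 2 male transcripts had 0 and 1.26 RPKM in the female library.

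The first developmental step compared was from egg to L3. 12611 transcripts were at least 4-fold higher in L3 and 14709 were at least 4-fold higher in egg. The transcripts higher in L3 held 91.9% of the L3 reads and 1.11% of the egg reads, and those higher in egg held 90.5% of the egg reads and 2.09% of the L3 reads. The direction followed the ending of the identifier, since 12147 of the 12611 higher in L3 were L3-ending (96.3%) and 14623 of the 14709 higher in egg were other-ending (99.4%). Within the other-ending transcripts, 464 were higher in L3. It stays open whether the L3-ending set holds separate copies of genes in the other-ending set, or RNA of another organism. The calls and folds with L3, here and in the comparisons with the adults, may therefore not be changes in expression between stages. The leading transcripts higher in L3 were c7041_g1_i1_L3s, with 82044 L3 reads and 0 egg reads (at least 6320-fold higher), and c30492_g1_i2_L3s (986 nt), with 111282 and 0 reads (at least 8573-fold higher). The leading transcripts higher in egg were c54023_g1_i1_other (378 nt), with 14662 egg reads against 2 L3 reads (31722-fold, 95% interval 8780 to 261960), and c58912_g1_i1_other (1243 nt), with 42634 against 10 reads (18448-fold, 10030 to 38473). Of the transcripts higher in egg, 2360 had fewer than 10 egg reads. Of those higher in L3, 9333 had 0 egg reads (74.0%). The median ratio of L3 to egg over the 6731 transcripts with RPKM of at least 1 in both was -0.74 on the log2 scale as deposited and 0.65 with median-ratio scaling. The L3-high share of the calls was 46.2% as deposited, 47.3% with equal sums, 54.3% with median-ratio scaling and 51.6% with pairwise scaling, so the direction with more transcripts depended on the scaling.

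From L3 to the adult female, 14837 transcripts were at least 4-fold higher in the female and 12660 at least 4-fold higher in L3. None of the 14837 was L3-ending (0 transcripts), while 12589 of the 12660 were (99.4%). The female-high transcripts held 86.7% of the female reads and 2.82% of the L3 reads. c56208_g1_i1_other led them, with 16592 female reads and 0 L3 reads (at least 7973-fold higher), followed by c54023_g1_i1_other, with 17699 against 2 reads (12758-fold, 3531 to 105352). On the L3 side were c28583_g1_i1_L3s, with 68273 L3 reads against 2 female reads (23679-fold, 6555 to 195530), and c17541_g1_i1_L3s (699 nt), with 60665 against 0 reads (at least 14027-fold higher). Scaling decided which direction held more transcripts: the L3-high share of all calls was 46.0% as deposited, 65.2% with median-ratio scaling over the 4940 transcripts with RPKM of at least 1 in all libraries, 55.8% with pairwise scaling and 44.8% with equal sums. As deposited, the 7878 transcripts with RPKM of at least 1 in both had a median log2 ratio of female to L3 of 1.03, against -1.19 with median-ratio scaling.

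From L3 to the adult male, 14929 transcripts were at least 4-fold higher in the male and 12868 at least 4-fold higher in L3. All 14929 male-high transcripts were other-ending (0 L3-ending), and 12762 of the 12868 L3-high ones were L3-ending (99.2%). The male-high transcripts were led by c55289_g2_i1_other, with 49744 male reads and 0 L3 reads (at least 22665-fold higher), and c60056_g2_i1_other, with 55858 against 0 reads (at least 25451-fold higher). The L3-high ones were led by c28583_g1_i1_L3s, with 68273 L3 reads against 0 male reads (at least 16649-fold higher), and c46464_g1_i1_L3s (617 nt), with 45812 against 1 read (33515-fold, 6015 to 1323801). The male-high share of calls was 53.7% as deposited, 41.8% with median-ratio scaling, 46.0% with pairwise scaling and 53.5% with equal sums, and the median log2 ratio of male to L3 over 7127 transcripts was 0.90 as deposited and -0.84 with median-ratio scaling.

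Adult male and female were the most alike pair of libraries. Of the transcripts with RPKM of at least 1 in either sex, 20569 differed by less than 2-fold on the log2(RPKM + 1) scale, and these held 63.4% of the female and 57.8% of the male reads. 3038 transcripts were at least 4-fold higher in the male and 1901 at least 4-fold higher in the female. The male-high transcripts held 23.3% of the male reads and 0.650% of the female reads, whereas the female-high ones held 11.7% of the female reads and 0.917% of the male reads. Large differences were more often male-high: 1154 transcripts were at least 16-fold higher in the male and 287 in the female. At RPKM of at least 10, 496 male transcripts had no female read and 93 female transcripts had no male read. At a 2-fold threshold the order of the counts turned, with 7273 male-high and 8143 female-high transcripts, and the counts were 5405 and 4972 with a pseudocount of 0.1 RPKM and 1404 and 575 with 5 RPKM. The male-high share of the calls was 61.5% as deposited, 76.2% with median-ratio scaling, 69.1% with pairwise scaling and 56.0% with equal sums. The median log2 ratio of male to female over 23471 transcripts with RPKM of at least 1 in both was -0.27 as deposited and 0.20 with median-ratio scaling.

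The leading male-high transcripts were c55289_g2_i1_other, with 49744 male reads and 0 female reads (at least 15722-fold higher), and c55289_g1_i2_other (382 nt), with 38479 against 0 reads (at least 12162-fold higher). These 2 share a component number, so their separate values are uncertain if reads were shared between them. The leading female-high transcripts were c60235_g1_i1_other (2199 nt), with 22609 female reads against 10 male reads (2384-fold, 1296 to 4973), and c54033_g1_i1_other (786 nt), with 6319 against 2 reads (3332-fold, 922 to 27521). In the egg library the female-high set held 9.44% of the reads and the male-high set 2.30%. Much of the former lay on few members. c64680_g1_i6_other alone held 3.62% of the egg reads, and c58912_g1_i1_other had 42634 of the 3033150 egg reads. The 9.44% therefore does not describe the female-high set as a whole. RPKM of at least 1 in egg was reached by 1089 of the 1901 female-high (57.3%), 1448 of the 3038 male-high (47.7%) and 12542 of the 20569 transcripts within 2-fold (61.0%). In L3 the same share was 15.9%, 4.71% and 28.9%.

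**Figure D2:**
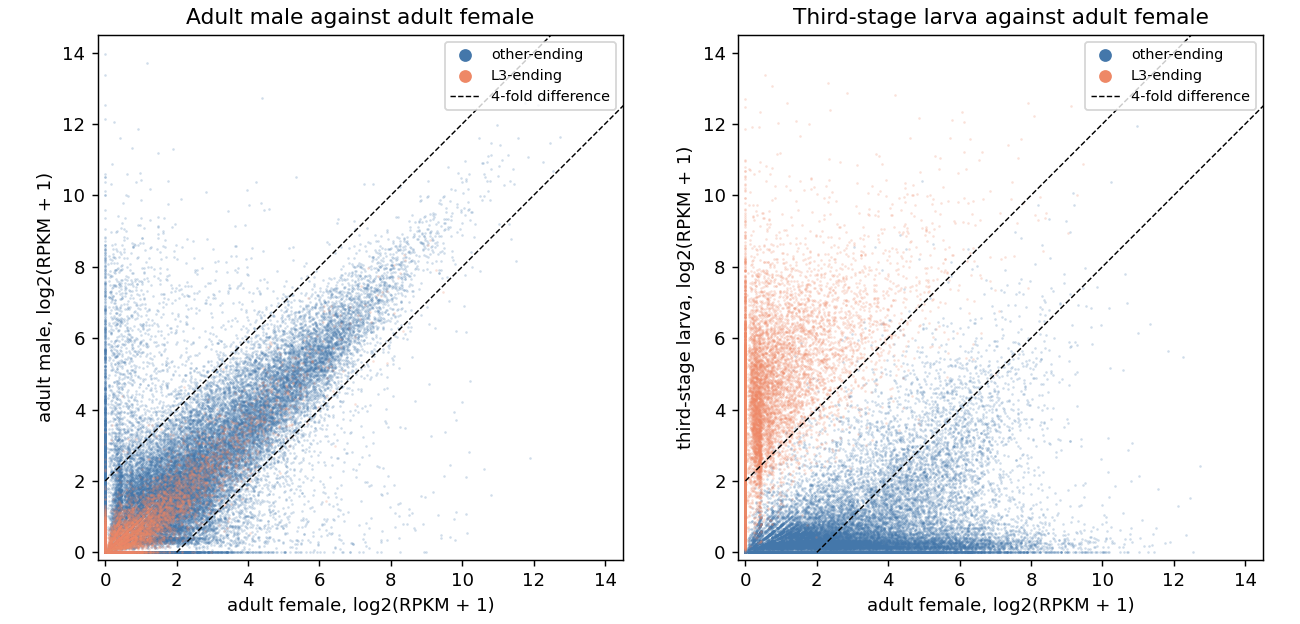
Log2(RPKM + 1) of each of the 54102 transcripts, with adult female on the x axis and adult male (left) or L3 (right) on the y axis, other-ending transcripts in blue, L3-ending ones in orange and dashed lines at a 4-fold difference. The left panel follows the diagonal with 3038 transcripts above and 1901 below the dashed lines, while in the right panel 12660 mostly orange transcripts lie above and 14837 blue transcripts lie below them.

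Between egg and the adults, the counts lay between those of the adult pair and those with L3. Compared with egg, 7311 transcripts were at least 4-fold higher in the female and 5420 lower. In the male 7598 were higher and 5764 lower. The egg-high transcripts held 38.7% of the egg reads in the comparison with the female and 45.0% in that with the male. The leading female-high transcripts were c78830_g1_i1_other (333 nt), with 2054 female reads and 0 egg reads (at least 228-fold higher), and c54224_g1_i2_other (558 nt), with 5396 against 1 read (1798-fold, 323 to 71021). The leading egg-high transcripts over both adults were c64680_g1_i6_other and c34494_g1_i1_L3s (1636 nt). The former had 109653 egg reads against 133 female reads (2475-fold, 2088 to 2956) and 23 male reads (15092-fold, 10057 to 23809). The latter had 19427 egg reads against 35 female reads (1666-fold, 1197 to 2393) and 2 male reads (30749-fold, 8511 to 253921). c64680_g1_i6_other is 1 of 3 listed transcripts that differ in the isoform field alone, so its values are uncertain if reads were shared among them. The leading male-high transcripts over egg were c55289_g2_i1_other, with 49744 male against 2 egg reads (7857-fold, 2175 to 64880), and c55289_g1_i2_other, with 38479 against 4 reads (3039-fold, 1187 to 11154). Egg-high calls with fewer than 10 egg reads numbered 913 against the female and 975 against the male. Of the adult-high calls, 4125 in the female (56.4%) and 4126 in the male (54.3%) had 0 egg reads. At the median length 0 egg reads allow up to 1.89 RPKM, so some of these calls may not be resolved at the egg depth. With median-ratio scaling the female-high share against egg went from 57.4% to 35.7% and the male-high share from 56.9% to 48.5%, while the adult-high transcripts stayed the larger group with pairwise scaling (56.7% and 54.9%) and with equal sums (62.9% and 58.8%). With median-ratio scaling the median log2 ratio to egg went from 0.04 to -0.79 for the female and from 0.09 to -0.27 for the male.

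**Figure D3:**
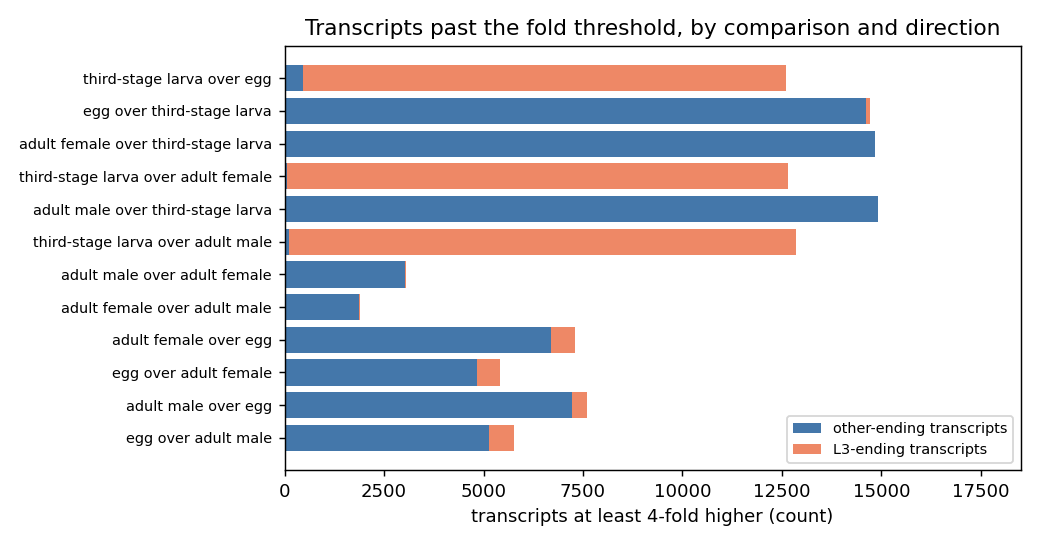
Number of transcripts (x axis) at least 4-fold higher in the first than in the second library of each row, divided into other-ending (blue) and L3-ending (orange) transcripts. Bars for L3 over another stage are mostly orange and those of another stage over L3 mostly blue, and the shortest bars are those of male over female (3038) and female over male (1901).

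Some transcripts were at least 4-fold above each of the other 3 libraries: 3541 in egg, 11598 in L3, 1024 in the adult female and 2312 in the adult male. These sets held 35.0% of the egg reads, 87.6% of the L3 reads, 7.86% of the female reads and 21.4% of the male reads. All but 28 of the 11598 L3 transcripts were L3-ending, and 3456 of the 3541 egg transcripts and all of the female and male ones were other-ending. The median length was 408 nt in the egg set, 557 nt in L3, 608 nt in the female and 655.5 nt in the male set. When the L3 library was left out, the egg, female and male sets came to 4032, 1161 and 2424 transcripts. This omission was chosen after the data were seen. The female set came to 459 with median-ratio scaling, 370 with a pseudocount of 5 RPKM, 2530 with a pseudocount of 0.1 RPKM and 4523 at a 2-fold threshold, and with a pseudocount of 5 RPKM the egg, L3 and male sets came to 1629, 5620 and 1179.

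Across the 50028 transcripts with RPKM of at least 1 in any library, log2(RPKM + 1) of male and female had a Pearson correlation of 0.74 and a Spearman correlation of 0.71. The values were 0.58 and 0.52 for female and egg, and 0.55 and 0.49 for male and egg. Those with L3 were below 0: Pearson -0.17 and Spearman -0.16 with egg, -0.13 and -0.19 with the female, and -0.20 and -0.27 with the male. Within each ending the L3 correlations were above 0. In other-ending transcripts Spearman's rho with L3 was 0.24 for egg, 0.37 for the female and 0.28 for the male, and in L3-ending transcripts it was 0.25, 0.55 and 0.53. The pooled negative values with L3 therefore did not hold within either set. These 6 pairs of correlations are across transcripts, which are not independent replicates, and no p-value is attached.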

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

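Among the transcripts named in the report, 4 went opposite ways in the 2 adult sexes when each was set against egg, by at least 4-fold each in the values as deposited. The difference was not tested, since each stage has 1 library. The named transcripts were picked for large differences, those between the sexes among them. With a large sex difference, any egg value well between the sexes gives opposite signs, so the choice favours this pattern. On the log2(RPKM + 1) scale, c60056_g2_i1_other was 9.44 higher in the male than in egg, and the female minus egg value was -3.09. For c55289_g1_i2_other the values were 11.20 in the male and -2.15 in the female, but the latter rests on 4 egg reads against 0 female reads, which allow up to 0.863 RPKM, so a 4-fold lower female level was not detectable at this depth. In the opposite direction, c60235_g1_i1_other had 5.84 in the female and -3.75 in the male, and c54033_g1_i1_other had 4.42 in the female and -5.02 in the male. Over all transcripts, 339 were higher in the male and lower in the female than in egg by this measure, and 64 were higher in the female and lower in the male. With at least 10 egg reads these counts were 312 and 60. With L3 in place of egg, and no minimum of reads, they were 2 and 1.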

How the results depend on the processing

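Of 203 alternative values for the 20 counts, 156 lay within 1.5 times the reported count and 47 did not. All counts of transcripts past the fold threshold stayed within 1.5 times with equal sums, with RPKM of at least 5, with at least 10 reads, at the egg depth and summed over isoforms, as did the 12 counts between pairs of stages with pairwise scaling, which was not run for the counts above all other stages. Dropping the filter on low values moved nothing, because a 4-fold difference at a pseudocount of 1 already requires more than 1 RPKM. The pseudocount had the widest effect. At 5 RPKM, L3 against egg gave 6220 and 6466 (higher in L3, in egg), female against L3 6380 and 6007, male against L3 6752 and 6221, male against female 1404 and 575, female against egg 2249 and 2113, and male against egg 2729 and 2334. The counts above each of the other stages were then 1629 for egg, 5620 for L3, 370 for the female and 1179 for the male. At 0.1 RPKM, 23651 were higher in female than L3, 23505 in male than L3, 5405 in male than female, 4972 in female than male, 13236 in female than egg and 13609 in male than egg. The female and male counts above the other stages were 2530 and 3897. At a 2-fold threshold, 24164 were higher in female than L3, 24021 in male than L3, 7273 in male than female, 8143 in female than male, 15773 in female than egg, 9911 in egg than female, 16014 in male than egg and 10153 in egg than male. The egg, female and male counts above the other stages were 6524, 4523 and 5282. Median-ratio scaling gave 8052 for female over L3, 958 for female over male, 3903 for female over egg and 459 for the female above the other stages. Its factors were 0.99 for egg, 0.38 for L3, 1.76 for the female and 1.27 for the male, and they rest on the 4940 transcripts shared by all libraries. The settings with at least 10 reads, the egg depth, sums over isoforms, pairwise scaling, other-ending transcripts and no L3 library were chosen after seeing the data. With other-ending transcripts alone, L3-high counts were 464 against egg, 71 against the female, 106 against the male and 28 above all. Detection at RPKM above 0 was 38450 in L3, and at RPKM of at least 5 it was 15560 in egg, 15134 in the female and 15165 in the male. Correlations are given as Pearson, then Spearman. With RPKM of at least 1 in all 4 libraries, they were -0.035 and -0.018 for L3 and egg, 0.866 and 0.859 for male and female, 0.510 and 0.536 for female and egg, and 0.514 and 0.525 for male and egg. They reversed to 0.074 and 0.118 for female and L3 and to 0.056 and 0.087 for male and L3. In other-ending transcripts they reversed to 0.280 and 0.239 for L3 and egg, 0.431 and 0.374 for female and L3, and 0.338 and 0.283 for male and L3, and were 0.650 and 0.558 for male and female, 0.501 and 0.411 for female and egg, and 0.446 and 0.359 for male and egg. With a pseudocount of 0.1, Pearson was -0.182 for L3 and egg, -0.192 for female and L3, -0.273 for male and L3, 0.720 for male and female, 0.543 for female and egg, and 0.516 for male and egg. The causes of these changes were not tested. All 96 alternative values of the 24 named differences kept their direction, between 7.09 and 17.29 on the log2 scale. These differences were picked as the largest, and the pseudocounts and scalings run could not have reversed them. Gene list medians and their alternatives were not run, since the table names no gene. No paired analysis was possible because each stage has 1 library. Depth limited egg most, where 1 read was worth 0.632 RPKM at the median length.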

Other observations

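Each set of transcripts also held some of the reads of the libraries it was poor in. The egg reads on L3-ending transcripts were concentrated, with 10 transcripts holding 63.9% of them, against 19.0% in the female and 16.1% in the male. The L3 reads on other-ending transcripts were spread more widely than these egg reads, with 10 transcripts holding 13.7% of them. Highest in egg RPKM among L3-ending transcripts were c38797_g1_i1_L3s and c10583_g1_i1_L3s, with 0.822% and 2.12% of all egg reads. Both were higher in egg (25445 and 12110 RPKM) than in L3 (653 and 947 RPKM). Of all L3-ending transcripts, 86 were at least 4-fold higher in egg than in L3, and 12147 were at least 4-fold higher in L3. Within L3-ending transcripts, male and female had a Pearson correlation of 0.92 and a Spearman correlation of 0.72 across transcripts.

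The tests of carry-over, stage regulation, separate copies and another organism were chosen after the L3 pattern was seen, the depth test of the sex counts was altered after its first value was seen, and the test at equal male and female depth was added later still. The first pattern is that L3 reads lie on L3-ending transcripts. At the egg depth, 12633 transcripts were still at least 4-fold higher in L3 than in the male, against 12868. The number of such calls thus depended little on the number of reads counted. Random thinning leaves the share of reads on each set of transcripts almost unchanged, so it could not test depth as a source of the pattern. Carry-over of L3 reads at a single rate was examined as a source of the reads elsewhere on L3-ending transcripts. Of the 105 such transcripts with L3 RPKM of at least 1000, 8 (7.62%) had no read in the other 3 libraries. At the median rate of 0.241%, at least 9.05 female reads would be expected for each of these 8. That argues against carry-over at the median rate as the only source. Carry-over at a lower rate beside other sources stays open, since the median rate includes any female reads of other origin. Stage regulation, separate copies of the same genes in the 2 sets and RNA of another organism in the L3 library all stay open. The shares computed for them restate the pattern and back none of them: 10.3% of the 3938 transcripts at RPKM of at least 10 and within 4-fold in egg, female and male were within 4-fold of the female value in L3 (64 of the 3938 are L3-ending), 2.29% of other-ending transcripts lay within 4-fold in all libraries, and 83.1% of L3 reads lay on transcripts with RPKM in both adults under 0.1 of that in L3. These 3 cannot be told apart without the transcript sequences, and the sequencing instrument of each library is not known either.

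The second pattern is the larger number of male-high than female-high transcripts, a ratio of 1.60. It is not accounted for by isoforms, with a ratio of 1.55 after summing over isoforms, or by the larger number of male reads, with a mean of 1.59 over 20 thinnings of the male library to the female depth (SD 0.00722 over thinnings). With all libraries thinned to the egg depth the mean over 20 thinnings was 1.31 (SD 0.0168, range 1.26 to 1.34), and 1 thinning gave 3499 male-high and 2675 female-high transcripts, both above the counts at full depth; this mean replaced a single thinning after its value, near the bound of 1.3 set beforehand, was seen. Median-ratio scaling, the scaling the test named beforehand, gave a ratio of 3.20, and pairwise scaling gave 2.24. These scalings raised the median log2 ratio of male to female from -0.27, to 0.20 with median-ratio scaling, which favours male-high calls. They therefore could not show whether scaling made the excess. Equal sums lowered this median to -0.41 and gave a ratio of 1.27, under the bound of 1.3 set beforehand. The excess was there under each scaling run, but its size depended on the scaling, and scaling as its cause stays undecided. The excess may also rest on the threshold or the pseudocount, since the male-high and female-high counts were 7273 and 8143 at 2-fold, 5405 and 4972 with a pseudocount of 0.1 and 1404 and 575 with a pseudocount of 5, and with 1 library per sex no biological explanation was tested.

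The third pattern is the lower number of transcripts with a read in egg, 28855 against 41318 in the female. At the egg depth the female library had 35641, still 23.5% more than egg, so the lower number of counted egg reads is not the whole cause on this list of transcripts. Thinning cannot undo an effect of depth on which transcripts were assembled and listed, so lower depth of the egg library stays open in that respect. Without the 100 transcripts with most egg reads and at equal depth the excess was 16.2%, so those transcripts are not the whole cause either, although they may account for a part. At the egg depth with all transcripts kept, L3 had 28070 transcripts with a read, fewer than the 28855 in egg.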
